A study of Mus musculus with 18 samples.

How the data were processed

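Gene expression was measured on 18 Affymetrix mouse arrays, each hybridised with RNA from CD8 T cells of F5 T cell receptor transgenic mice. Per the labels' protocols, naive cells and memory cells were sorted from spleen. The memory cells, called TIM cells in the labels, came from mice immunised with a peptide of the transgenic receptor's antigen and were taken on day 45. Cultured cells spent 20 hours with IL-7 at 10 ng/mL, IL-4 at 20 ng/mL, both, or medium alone. Per the labels' protocols, RNA was amplified in a linear reaction and labelled with biotin by in vitro transcription before hybridisation. The deposited values are RMA values on a log2 scale, 1 per probe set and array, background-corrected and quantile-normalised by the authors, per the submitters' processing notes and the values themselves. The notes name RMA and limma with no version. The design text states that naive populations and memory populations were sorted and that samples of them were then cultured. The titles call the ex vivo arrays biological replicates and the cultured arrays only replicates. No label says that a replicate number marks a shared population or separate animals, so arrays were treated as independent replicates of their group.

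The table held 45101 probe sets, 64 of them array controls. The annotation used for the array gave 34958 probe sets exactly 1 gene symbol, 932 several symbols and 9211 none. Probe sets with several symbols or none were left out of the tests by gene. The Entrez IDs of 34754 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols. Of several probe sets of a gene, the one with the highest mean over all 18 arrays stood for the gene, which left 18194 genes. A gene was tested when its probe set lay above the 40th percentile of all values, 4.06 on the log2 scale, on at least 2 arrays. This filter kept 13770 genes and left out 4424. The filter value is a percentile and not a measured background, and the background of single probe sets is not known. The number of arrays limits the precision of each value, and p-values measure the spread between these arrays, not between further cell populations. For the hybridisation itself, the 3' minus 5' difference of the array controls ran from 2.07 to 3.36 for Gapdh and from 1.63 to 2.25 for Actb on the log2 scale. For Gapdh it was 2.07 to 2.69 on ex vivo arrays, 2.35 on the array labelled memory in medium, replicate 2, and 2.67 to 3.36 on the other cultured arrays. At most 34 probe sets had identical values in any pair of arrays. The most similar pair, memory IL-7 array 1 and medium array 1, differed with an SD of 0.23 (log2) over the genes tested. The array labelled memory in medium, replicate 2, and ex vivo memory array 2 differed with an SD of 0.24. Both values lie below the lowest SD within a group (0.26), so they do not exclude that 2 arrays carry the same RNA.

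The 8 groups and their sizes were taken from the labels. Each comparison was a contrast between group means in a single linear model over all 18 arrays, fitted with limma 3.58.1 in R 4.3.3, with moderated variances (10 residual and 4.13 prior degrees of freedom), two-sided tests and Benjamini-Hochberg adjustment over the genes tested. A gene was counted as higher or lower at an adjusted p under 0.05. The model had no replicate block. The comparisons were IL-4 against no IL-4 in memory cells with IL-7, in memory cells without IL-7 and in naive cells with IL-7; IL-7 against no IL-7 in memory cells without and with IL-4; memory against naive cells ex vivo; and cultured against ex vivo cells, in medium for memory cells and with IL-7 for naive cells. The difference between the IL-4 responses of memory and naive cells, and the interaction of IL-4 and IL-7 in memory cells, were tested as contrasts of contrasts. Where a group is left with a single array, limma takes its spread from the other groups.

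Lists of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a comparison, and again with the correlation estimated from the data. Each list's members were also counted as higher, lower or not past the test, both over all genes and adjusted over the list alone. The lists, with the number of members tested, were IL-7 and STAT5 responsive genes (21), NK-type receptors (15), cytotoxic effector genes (19), memory CD8 genes (24), naive CD8 genes (24), proliferation (26), interferon-stimulated genes (26), glycolysis (18), cholesterol synthesis (18), the unfolded protein and amino acid response (20), immediate early genes (22), the BCL2 family (14), ribosome biogenesis (23), cytokine receptors (23), homing molecules (22), inhibitory receptors (10) and IL-4 and STAT6 responsive genes (17). Markers were listed for B cells (6), macrophages and other myeloid cells (8), cells with MHC class II (9), CD4 T cells (3), NK cells (4), red cell precursors (4), platelets (4) and CD8 T cells (8). Some genes are in several lists; 10 members of the STAT5 list, 7 of the STAT6 list and all of the NK cell markers are also in another.

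The genes named are the 10 largest rises and the 10 largest falls of each of the 3 IL-4 comparisons, of the 2 IL-7 comparisons and of the ex vivo comparison, and the 5 largest each way elsewhere, among genes past the threshold whose arrays do not overlap between the groups. Added to these are the 4 members of a described list with the largest absolute change, and Klrk1, Hcst, Il4ra, Eomes, Il7r, Bcl2 and Cd8a in every comparison. Comparisons, tests, the filter, lists and these rules were fixed before the data were examined. Shared responses were described by a correlation across genes, which are not independent replicates. For comparisons with the same medium arrays, 100 simulations of unchanged groups gave the value that shared controls alone produce if all groups have the same spread per gene. Among other probe sets of the named genes past the threshold, members named only for a list left out, 6 of 66 gene-by-comparison values had the opposite sign. None of these 6 was past the threshold.

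The model was tested on simulated data for IL-4 in memory cells with IL-7. It recovered 27 of 50 genes changed by 1 on the log2 scale, 49 of 50 changed by 2, and all 50 changed by 3 and all 50 changed by 4; 9 unchanged genes were called. Camera called a shifted list and 0 random lists. The simulated genes varied independently, so this does not test lists whose members vary together. The alternatives tried were no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, cyclic loess on top of RMA, limma with trend and robust variances, a fit of only the groups compared, a replicate block, a minimum log2 change of 1, an estimated correlation for the lists, and leaving out each array in turn. Leaving out the array labelled memory in medium, replicate 2, in every comparison, also together with a block, was chosen after seeing the data. Image files of the arrays were not used here.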

Results

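The data are 18 arrays of RNA from sorted CD8 T cells in 8 groups. Naive cells were measured ex vivo, directly after sorting (2 arrays), after 20 hours with IL-7 (2 arrays) and after 20 hours with IL-4 and IL-7 (2 arrays). Memory cells were measured ex vivo (4 arrays) and after 20 hours in medium alone, with IL-7, with IL-4, or with both cytokines (2 arrays each). IL-7 and IL-4 are cytokines whose receptors share a common chain. The design asks what IL-4 changes in naive and memory CD8 T cells, with memory cells in medium and with IL-7 for comparison. Array medians lay between 4.62 and 4.76 on the log2 scale of the RMA values. The array labelled memory in medium, replicate 2, correlated best with ex vivo memory array 2 (r = 0.995 over the genes tested) and less with the other medium array (r = 0.956). The number of genes past the threshold in each comparison is given with and without that array.

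**Figure D1:**
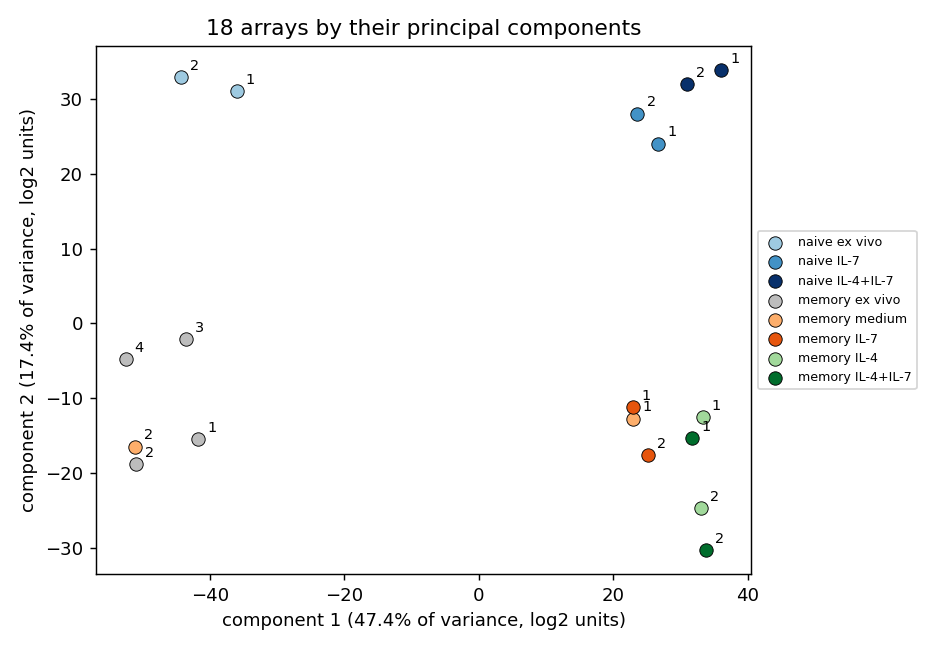
Principal components 1 and 2 of the 18 arrays over the genes tested, which hold 47.4% and 17.4% of the variance (axes in component scores); each point is an array, coloured by group and numbered by replicate. Ex vivo arrays lie at the left and cultured arrays at the right, except that the array labelled memory in medium, replicate 2, lies beside ex vivo memory array 2.

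In memory cells cultured with IL-7, IL-4 lowered Klrk1, the gene of the activating receptor NKG2D, and Klrd1, the gene of the receptor subunit CD94. Klrk1 fell by 1.82 on the log2 scale (SE 0.23, adjusted p = 0.000752, limma, n = 2 and 2), from a mean of 6.50 to 4.68. Klrd1 fell by 2.78 (SE 0.41, adjusted p = 0.00224), from 12.49 to 9.71. Hcst, which encodes the NKG2D adaptor DAP10, did not pass the test (log2 change 0.48, SE 0.35, adjusted p = 0.565). Both falls stayed past the threshold without any 1 of the 4 arrays compared. The granzyme gene Gzma went the other way and rose 17.0-fold, by 4.09 (SE 0.64, adjusted p = 0.00359). It missed the threshold without IL-4 and IL-7 array 2 (adjusted p = 0.0565) or without IL-7 array 1 (adjusted p = 0.0589). The chemokine gene Ccl5 fell by 1.63 (SE 0.34, adjusted p = 0.0261), and Gzmb did not pass (log2 change 2.24, adjusted p = 0.137).

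The largest rise of this comparison was in Frmd4b, a gene for a scaffold protein of the FERM family, at 6.97 (SE 1.16, adjusted p = 0.00557). Of its other probe sets, the brightest changed by 4.82 (adjusted p = 0.00917) and the dimmest by 0.13 (adjusted p = 0.762). The uncharacterised gene D630039A03Rik rose by 5.40 (SE 0.26, adjusted p = 6.96e-08), the carbonyl reductase gene Cbr3 by 5.35 (SE 0.28, adjusted p = 1.28e-07), and Pros1, which encodes protein S, by 4.52. The stress-response gene Gadd45g rose 27.9-fold. Gm4951, the hexose transporter gene Slc2a6, Metrnl and the IL-2 receptor gene Il2ra rose by 4.27, 4.22, 4.10 and 3.92. The means of Frmd4b (4.01), Gm4951 (3.86), Slc2a6 (4.06) and Metrnl (3.99) with IL-7 alone lay at or under the filter value of 4.06, so the size of these rises is uncertain. The largest falls were in Reck at -3.36 (SE 0.42, adjusted p = 0.000584), the transcription factor gene Myb at -3.21 (SE 0.56, adjusted p = 0.0075), the ubiquitin ligase gene Neurl3 at -2.98 and the class II accessory gene H2-Ob at -2.97. Pxylp1, Lypd6b, the scaffold gene Ahnak, Mir1931 and Tmem237 fell by between 2.07 and 2.57. D630039A03Rik, Cbr3, Gadd45g, Pros1, Gm4951, Slc2a6, Metrnl, Reck, Neurl3, H2-Ob and Pxylp1 stayed past the threshold without any 1 of the 4 arrays. Frmd4b missed it without IL-7 array 1 (adjusted p = 0.0515) or array 2 (adjusted p = 0.0726), and Myb without IL-4 and IL-7 array 1 (adjusted p = 0.0849) or IL-7 array 2 (adjusted p = 0.107). Il2ra, Lypd6b and Tmem237 missed it without each of the 4 arrays, at adjusted p of 0.12 to 0.254. Ahnak and Mir1931 missed it without IL-4 and IL-7 array 2, IL-7 array 1 or IL-7 array 2 (adjusted p 0.072 to 0.489).

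In all, 249 of 13770 genes passed, of which 167 rose and 82 fell. Without the array labelled memory in medium, replicate 2, which is in neither group but enters the pooled spread, 538 passed (304 rose and 234 fell) and all 249 were among them. The count was 147 (75 up and 72 down) without IL-4 and IL-7 array 1, 99 without its array 2, 76 without IL-7 array 1 and 78 without IL-7 array 2. The IL-4 receptor gene Il4ra rose by 3.05 (SE 0.60, adjusted p = 0.0175). It missed the threshold without IL-4 and IL-7 array 1, its array 2, IL-7 array 1 or IL-7 array 2. Its change was then 2.94, 3.16, 3.19 and 2.91, from fits that left 1 array in a group. Eomes, a transcription factor gene of memory cells, did not pass (log2 change 2.11, SE 0.66, adjusted p = 0.142), though another of its probe sets did (1.73, adjusted p = 0.0133). Cd8a did not pass (0.48, adjusted p = 0.37). The IL-7 receptor gene Il7r did not pass (log2 change -1.24, adjusted p = 0.0933) unless the array labelled memory in medium, replicate 2, was left out (adjusted p = 0.00251). Bcl2 did not pass (1.04, adjusted p = 0.21) unless IL-7 array 1 was left out (adjusted p = 0.0258), and of its 4 other probe sets 1 passed (1.84, adjusted p = 0.0239) and 3 did not (1.19, 0.27 and -1.07).

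Interferon-stimulated genes were the list with the smallest p-value under IL-4 in these cells. Of 26 tested, 10 rose, 0 fell and 16 did not pass over all genes, while 16 rose when adjusted over the list alone. Their mean change was 1.35 (camera adjusted p = 5.77e-15), and adjusted p = 0.104 with an estimated correlation. Rtp4 rose by 2.84, Zbp1 by 2.82, Gbp2 by 2.57 and Ifit1 by 2.51 (adjusted p 0.00017 to 0.00636). Of the 17 IL-4 and STAT6 genes, 5 rose and 0 fell, 8 when adjusted over the list alone, with a mean of 1.41 (adjusted p = 4.53e-07, and adjusted p = 0.104 with an estimated correlation). Beside Il4ra, the signalling genes Cish and Socs2 rose by 2.98 and 2.62 and the transcription factor gene Xbp1 by 2.73. Of the 21 IL-7 and STAT5 genes, 5 rose and 1 fell, 10 and 2 when adjusted over the list alone, with a mean of 0.82 (adjusted p = 0.000116, and adjusted p = 0.104 with an estimated correlation). Igf1r fell by 2.05 (adjusted p = 0.00136). Of 18 cholesterol synthesis genes 3 rose and 0 fell, 4 when adjusted over the list alone (mean 0.56, adjusted p = 3.43e-05, and adjusted p = 0.104 with an estimated correlation). Mvd rose by 1.76, Fdps by 1.06 and Dhcr7 by 0.91, and Fdft1 did not pass (0.87, adjusted p = 0.0841).

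The unfolded protein and amino acid list was also higher with IL-4 (mean 0.53, adjusted p = 0.0165, and adjusted p = 0.758 with an estimated correlation), with no member past the test over all genes in limma and 5 of 20 higher when adjusted over the list alone. It missed the threshold without IL-4 and IL-7 array 1 (adjusted p = 0.0812). Ddit3 (1.38), Slc7a5 (1.17), Shmt2 (1.13) and Psat1 (1.11) had its largest changes and none passed. The naive CD8 list was lower (mean -0.16, adjusted p = 0.0318, and adjusted p = 0.209 with an estimated correlation), although its 1 member past the test over all genes, Treml2, rose by 2.55 (adjusted p = 0.000949); 2 rose and 6 fell of 24 when adjusted over the list alone. It missed the threshold without IL-4 and IL-7 array 2 (adjusted p = 0.183) or IL-7 array 1 (adjusted p = 0.149). NK-type receptors (adjusted p = 0.128, with the falls of Klrk1 and Klrd1), cytotoxic effector genes (0.532), memory CD8 genes (0.153) and homing molecules (0.125) did not pass as lists. NK-type receptors passed as lower without IL-7 array 2 (adjusted p = 0.0161) and homing molecules as lower without IL-7 array 1 (adjusted p = 0.00685), but not with an estimated correlation (adjusted p = 0.284 and 0.0609). Proliferation (0.284), glycolysis (0.997), immediate early genes (0.392), the BCL2 family (0.507), ribosome biogenesis (0.627), cytokine receptors (0.716) and inhibitory receptors (0.627) did not pass, nor did any marker list (0.518 to 0.997).

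**Figure D2:**
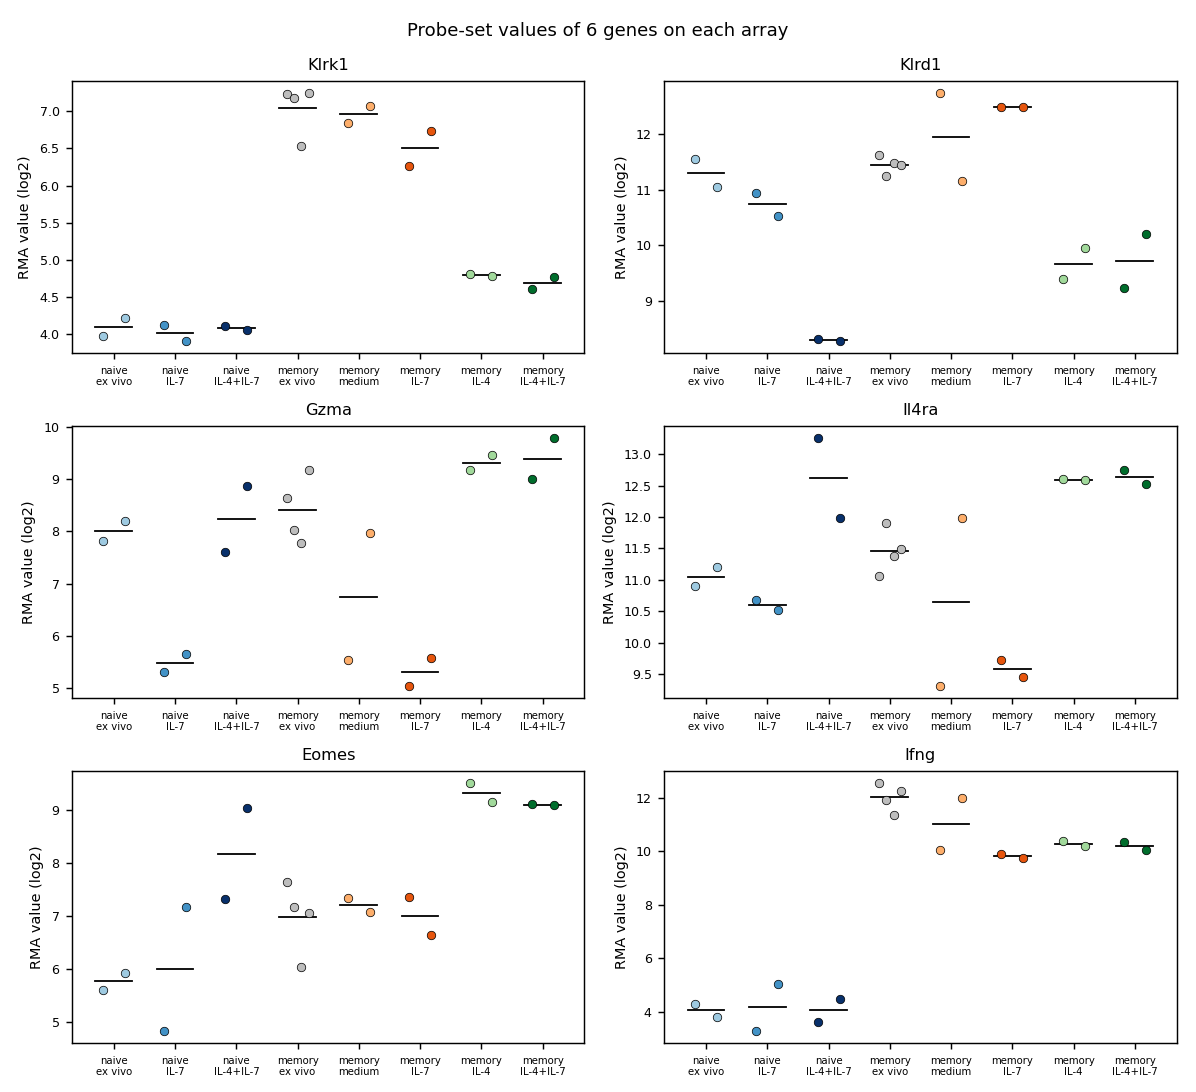
RMA values (log2, vertical axis) of Klrk1, Klrd1, Gzma, Il4ra, Eomes and Ifng on each of the 18 arrays, by group (horizontal axis); points are arrays and lines are group means. Klrk1 has means of 6.50 with IL-7 and 4.68 with IL-4 and IL-7 in memory cells, and of 4.01 and 4.08 in naive cells.

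Without IL-7, IL-4 lowered Klrk1 in memory cells as well, by a log2 change of -2.17 (SE 0.23, adjusted p = 0.000136, limma, n = 2 and 2), from a mean of 6.96 in medium to 4.79. Klrd1 fell by 2.28 (SE 0.41, adjusted p = 0.0093). The survival gene Bcl2 rose 4.12-fold, by 2.04 (SE 0.38, adjusted p = 0.0109), and missed the threshold without IL-4 array 1 (adjusted p = 0.153). Klrk1 stayed past the threshold without any 1 of the 4 arrays, at -2.06 (adjusted p = 0.00141) without the array labelled memory in medium, replicate 2. Hcst (-0.50, adjusted p = 0.597) and Eomes (2.13, adjusted p = 0.143) did not pass, though another probe set of Eomes did (1.51, adjusted p = 0.032). Il4ra (1.95, adjusted p = 0.14) and Il7r (-0.38, adjusted p = 0.71) did not pass either, but did without that medium array (3.28, adjusted p = 0.000449, and -1.14, adjusted p = 0.0263). Cd8a (0.83, adjusted p = 0.1) did without medium array 1 (1.18, adjusted p = 0.00366).

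D630039A03Rik rose by 6.12 (SE 0.26, adjusted p = 1.24e-08), Pros1 by 5.16 (SE 0.33, adjusted p = 7.87e-07), Cbr3 by 4.78 (SE 0.28, adjusted p = 5.98e-07), the secreted protein gene Tafa3 by 4.62 and the nuclear receptor coactivator gene Ncoa7 by 4.49. Gm4951, Gm17767, the myosin gene Myo6, Slc2a6 and the methyltransferase gene Etfbkmt rose by 3.86 to 4.29. The medium means of D630039A03Rik (4.01), Gm4951 (3.92), Gm17767 (3.51) and Slc2a6 (3.98) lay under the filter value, so the size of these rises is uncertain. The largest falls were in Myb at -4.28 (SE 0.56, adjusted p = 0.000843), the immediate early gene Fosb at -4.16 (SE 0.95, adjusted p = 0.0363), Neurl3 at -3.89 (SE 0.43, adjusted p = 0.000162) and the signalling regulator Rgs2 at -3.32. Ahnak, H2-Ob, Fos, Reck, Lypd6b and Ctla2b fell by 2.33 to 3.04. Without the array labelled memory in medium, replicate 2, Fosb (-2.32, adjusted p = 0.266) and Fos (-1.86, adjusted p = 0.229) no longer passed, and the other genes of this paragraph did. Fosb, Fos, Rgs2, Etfbkmt and Lypd6b missed the threshold without IL-4 array 1 or without IL-4 array 2 (adjusted p 0.106 to 0.312), and Reck and Ctla2b without IL-4 array 2 (adjusted p 0.0837 and 0.0673).

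Here 267 genes passed, 174 up and 93 down. There were 212 (131 up and 81 down) without the array labelled memory in medium, replicate 2, of which 131 were among the 267. Without medium array 1, so that the array labelled replicate 2 alone stood for medium, there were 2364. The count was 73 without IL-4 array 1 and 86 without IL-4 array 2. Interferon-stimulated genes again rose, with 8 of 26 up and 0 down over all genes and 15 up when adjusted over the list alone (mean 1.12, adjusted p = 1.65e-12, and adjusted p = 0.147 with an estimated correlation). Rtp4 rose by 2.62, Gbp2 by 2.31 and Ifit1 by 2.25, and Ifit3 did not pass (2.26, adjusted p = 0.0957).

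Of the IL-7 and STAT5 genes, 5 rose and 1 fell, 13 and 1 when adjusted over the list alone (mean 0.85, adjusted p = 1.61e-05, and adjusted p = 0.129 with an estimated correlation). Il2ra rose by 3.85, Socs2 by 3.34 and Lta, the lymphotoxin gene, by 1.98. Of the cholesterol genes 2 rose and 0 fell, 10 when adjusted over the list alone (mean 0.55, adjusted p = 4.43e-06, and adjusted p = 0.129 with an estimated correlation), among them Mvd by 1.72 and Msmo1 by 1.20. Of the IL-4 and STAT6 genes 3 rose and 0 fell, 8 when adjusted over the list alone (mean 0.91, adjusted p = 0.000263, and adjusted p = 0.181 with an estimated correlation). The medium arrays lay far apart for this list (mean 7.17, SD 0.81), so the size of its change depends on them. These last 3 lists passed without the array labelled memory in medium, replicate 2, also with an estimated correlation (adjusted p = 0.0332, 0.0155 and 0.0155). Without medium array 1 they did not pass (adjusted p = 0.111, 0.135 and 0.602).

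Immediate early genes had a mean of -1.77 (adjusted p = 9.66e-11, and adjusted p = 0.181 with an estimated correlation), with 0 up and 4 of 22 down, 9 when adjusted over the list alone. Without the array labelled memory in medium, replicate 2, the list mean less that of all genes was only -0.458, and the list did not pass. NK-type receptors were lower (0 up and 2 of 15 down, 3 when adjusted over the list alone; mean -0.58, adjusted p = 0.000459, and adjusted p = 0.147 with an estimated correlation). Memory CD8 genes, naive CD8 genes, ribosome biogenesis and homing molecules were lower at adjusted p = 0.0211, 0.0359, 0.00441 and 0.0116, and none passed with an estimated correlation (adjusted p = 0.42, 0.181, 0.481 and 0.181). The first 3 of these did not pass without the array labelled memory in medium, replicate 2 (adjusted p = 0.214, 0.0529 and 0.214). Without IL-4 array 2 they did not pass either (0.141, 0.331 and 0.109). Homing molecules did not pass without IL-4 array 1 (0.0655) or medium array 1 (0.121), nor naive CD8 genes without medium array 1 (0.165). Cytotoxic effector genes and the unfolded protein list, not past the test with all arrays (adjusted p = 0.439 and 0.849), were higher with IL-4 without the array labelled memory in medium, replicate 2 (0.0376 and 0.022), and lower with IL-4 without medium array 1 (0.0134 and 0.014). None of these 4 calls held with an estimated correlation (adjusted p 0.516 to 0.651).

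In naive cells cultured with IL-7, IL-4 raised Cbr3 by 5.28 (SE 0.28, adjusted p = 3.1e-07, limma, n = 2 and 2), Pros1 by 4.71 (SE 0.33, adjusted p = 1.75e-06) and Slc2a6 by 4.40 (SE 0.28, adjusted p = 1.31e-06). Ecm1, an extracellular matrix gene, fell by 3.59 (SE 0.25, adjusted p = 1.75e-06). Klrd1 fell by 2.44 (SE 0.41, adjusted p = 0.00698), from 10.73 to 8.30. It missed the threshold without IL-7 array 1 (adjusted p = 0.127) or IL-4 and IL-7 array 1 (adjusted p = 0.0578). Klrk1 did not pass (log2 change 0.06, SE 0.23, adjusted p = 0.973), with means of 4.01 and 4.08 that lie next to the filter value of 4.06. Bcl2 (0.02, adjusted p = 0.997), Cd8a (0.17, adjusted p = 0.913) and Hcst (-0.37, adjusted p = 0.839) did not pass. Il4ra (2.02, adjusted p = 0.169) passed without IL-4 and IL-7 array 2 (2.66, adjusted p = 0.0441) or without the array labelled memory in medium, replicate 2 (adjusted p = 0.00348). Il7r (-0.85, adjusted p = 0.465) passed without the latter (adjusted p = 0.0383). Eomes (2.18, adjusted p = 0.187) passed without IL-7 array 2 (3.35, adjusted p = 0.0292).

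Frmd4b rose by 6.09 (SE 1.16, adjusted p = 0.0183), Ncoa7 by 4.20 (SE 0.35, adjusted p = 1.32e-05), the phosphatase gene Dusp10 by 4.01, Tafa3 by 3.89 and the phosphatase gene Ptpn3 by 3.46 (SE 0.26, adjusted p = 4.16e-06). The mean of Ptpn3 with IL-7 alone (3.65) lay under the filter value. The prion protein gene Prnp rose by 3.32 and Spsb1 by 3.25. Beside Ecm1 and Klrd1, Ctla2a, the vimentin gene Vim, the IL-18 receptor gene Il18r1, Olfml3 and Atp10a fell by 2.00 to 2.88, and Tent5a, Fxyd7 and Gpr34 by 1.92 to 1.96. Frmd4b missed the threshold without IL-7 array 1 (adjusted p = 0.256) or IL-4 and IL-7 array 1 (adjusted p = 0.122). Dusp10, Spsb1, Ctla2a, Tent5a and Gpr34 missed it without IL-7 array 1, IL-7 array 2 or IL-4 and IL-7 array 1 (adjusted p 0.0735 to 0.332). Vim missed it without IL-7 array 1, IL-7 array 2 or IL-4 and IL-7 array 2 (0.0822 to 0.234). Fxyd7 missed it without IL-7 array 2 (0.42) or IL-4 and IL-7 array 1 (0.335).

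Of the genes tested in naive cells, 173 passed, 121 up and 52 down, and 290 (192 up and 98 down, all 173 among them) without the array labelled memory in medium, replicate 2. The count was 50 without IL-7 array 1, 80 without IL-7 array 2, 78 without IL-4 and IL-7 array 1 and 672 (233 up and 439 down) without IL-4 and IL-7 array 2. Interferon-stimulated genes rose, with 5 of 26 up and 0 down over all genes and 15 up when adjusted over the list alone (mean 1.01, camera adjusted p = 1.24e-15, and adjusted p = 0.17 with an estimated correlation). The list mean in naive cells was 9.06 ex vivo, 8.04 with IL-7 and 9.05 with IL-4 and IL-7 (SD 0.46, 0.43 and 0.31). With IL-4 it thus stood near the ex vivo level and not above it. Irf7 rose by 2.05 and Rtp4 by 2.00 (adjusted p = 0.00893 and 0.00311), and Ifit3 (2.17) and Oasl2 (2.14) did not pass. Of the IL-4 and STAT6 genes 2 rose and 0 fell, 6 when adjusted over the list alone (mean 1.06, adjusted p = 5.27e-08, and adjusted p = 0.17 with an estimated correlation). Xbp1 rose by 2.80 (adjusted p = 0.00243). Memory CD8 genes (adjusted p = 0.0341) and ribosome biogenesis (adjusted p = 0.00371) were lower, and both had adjusted p = 0.808 with an estimated correlation. Neither passed without IL-7 array 2 (0.73 and 0.134) or without IL-4 and IL-7 array 1 (0.763 and 0.0711). The unfolded protein list, not past the test with all arrays (adjusted p = 0.559), was higher without these same arrays (0.000643 and 0.00103), and immediate early genes (adjusted p = 0.4) were lower without IL-7 array 1 (0.024), none of them with an estimated correlation (adjusted p = 0.917, 0.945 and 0.764). The IL-7 and STAT5 list did not pass in naive cells (mean -0.13, adjusted p = 0.559).

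**Figure D3:**
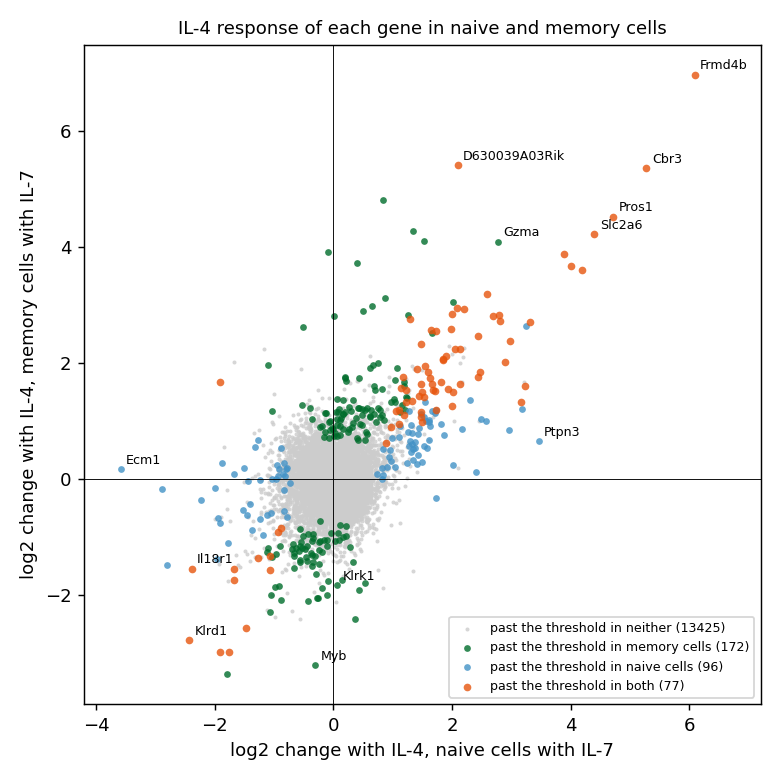
Log2 change of each of the 13770 genes with IL-4 in naive cells (horizontal axis) and in memory cells (vertical axis), both with IL-7; each point is a gene, coloured by the comparison in which it passed the threshold. Frmd4b, Cbr3, Pros1 and Slc2a6 lie at upper right, Klrd1 at lower left, and Ecm1 and Ptpn3 moved in naive cells by -3.59 and 3.46.

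The IL-4 responses overlapped. The numbers given for independent lists are a reference and not a test. All comparisons use 1 estimate of spread per gene, so genes of small spread are favoured in every list. In memory cells with and without IL-7, 97 genes rose in both comparisons, where independent lists would share 2.11, and 38 fell in both, where they would share 0.554. Across the 381 genes past the threshold in either, the changes had r = 0.893 and 99.2% had the same direction; genes are not independent replicates, and across all genes r was 0.514 with 61.1% in the same direction. Without the array labelled memory in medium, replicate 2, 118 rose in both (2.89 by independent lists) and 65 fell in both (1.38), with r = 0.949 across 567 genes. Between memory and naive cells with IL-7, 64 genes rose in both (1.47 by independent lists), 12 fell in both (0.31) and 1, Myo6, rose in memory cells and fell in naive cells. Here r was 0.701 across 345 genes, 84.9% of them in the same direction, and 0.313 across all genes with 48.4% in the same direction. With that array left out, 105 rose in both (4.24), 29 fell in both (1.67) and 2, Myo6 and Tnfrsf18, rose in memory cells and fell in naive cells. Then r was 0.674 across 692 genes, 79.3% of them in the same direction. In all 3 IL-4 comparisons 54 genes rose and 10 fell, where independent lists would share 0.0185 and 0.00209. Without that array 68 rose, 48 of the 54 among them, and 22 fell, all 10 among them (0.0403 and 0.0098 by independent lists). Cbr3, Pros1, Slc2a6, Ncoa7, Tafa3, D630039A03Rik, Prnp, Xbp1, Treml2, Rtp4 and Gbp2 were among the 54 that rose, and Klrd1, H2-Ob, Neurl3 and Pxylp1 among the 10 that fell.

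A test of the difference between memory and naive cells asked which genes answer IL-4 unequally. Ecm1 differed by 3.76 (SE 0.35, adjusted p = 0.00045, limma, n = 2 in each of 4 groups), with a fall of 3.59 in naive cells and a change of 0.17 (adjusted p = 0.78) in memory cells. With IL-7 alone Ecm1 stood at 10.1 and 10.3 on the naive arrays and already at 6.045 and 6.15 on the memory arrays. It thus had a lower starting level in memory cells, near that of naive cells with IL-4 (6.40 and 6.84). Myo6 differed by 3.59 (SE 0.47, adjusted p = 0.00583), with 1.68 in memory cells and -1.91 in naive cells. D630039A03Rik differed by 3.31 (SE 0.37, adjusted p = 0.00205), rising by 5.40 in memory cells and by 2.10 in naive cells. Its values with IL-7 alone were 4.97 and 4.82 on memory arrays and 9.09 and 8.88 on naive arrays, so starting levels differed here too. Gm17767 differed by 3.32 (adjusted p = 0.00583) and Lta by 3.08 (adjusted p = 0.0461). Ptpn3 (-2.81, adjusted p = 0.00583), Papss2 (-2.05, adjusted p = 0.0154) and Dhrs3 (-1.76, adjusted p = 0.0154) responded more in naive cells, as did H2-Q2 (-2.28, adjusted p = 0.0154), whose probe set may share sequence with other class I genes. The tenth gene, Tnfrsf18, named after its values were seen, differed by 2.20 (adjusted p = 0.0461). With IL-7 alone the means of Ptpn3 (3.58 in memory and 3.65 in naive cells), Dhrs3 (3.89 and 3.64) and H2-Q2 (2.57 and 2.93) lay under the filter value, as did Gm17767 in memory cells (3.81) and H2-Q2 in memory cells with both cytokines (2.69). The size of these differences is uncertain. Klrk1 lay next to the filter value in naive cells with IL-7, with or without IL-4, so a fall there could hardly show. The difference for Klrk1 was -1.88 (SE 0.33, adjusted p = 0.0597), which passed without the array labelled memory in medium, replicate 2 (adjusted p = 0.0389), or without naive IL-4 and IL-7 array 2 (-1.91, adjusted p = 0.0227). The differences for Eomes (-0.07), Il4ra (1.03), Bcl2 (1.02), Hcst (0.85), Il7r (-0.39) and Cd8a (0.31) did not pass.

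These 10 genes, 6 with a positive and 4 with a negative difference, became 20 without the array labelled memory in medium, replicate 2, with all 10 among them. The count was 4 without naive IL-7 array 1, 4 without naive IL-4 and IL-7 array 1, 368 without naive IL-4 and IL-7 array 2, 2 without memory IL-4 and IL-7 array 2 and 5 without memory IL-7 array 2. Ecm1 and D630039A03Rik passed without each of these arrays; Myo6 and Gm17767 passed in every case but without memory IL-4 and IL-7 array 2 (adjusted p = 0.0666 and 0.0627). Ptpn3 did not pass without naive IL-7 array 1, naive IL-4 and IL-7 array 1 or memory IL-4 and IL-7 array 2 (adjusted p 0.0512 to 0.0631). Lta missed it without naive IL-7 array 1 (0.201) or 2 (0.223), naive IL-4 and IL-7 array 1 (0.112), memory IL-4 and IL-7 array 1 (0.14) or 2 (0.0789), or memory IL-7 array 2 (0.267). H2-Q2 and Papss2 missed it without naive IL-7 array 1 (0.121 for both), naive IL-4 and IL-7 array 1 (0.0681 and 0.072), memory IL-4 and IL-7 array 2 (0.0983 and 0.0807) or memory IL-7 array 2 (0.148 for both). H2-Q2 also missed it without memory IL-7 array 1 (0.0572), and Papss2 without memory IL-4 and IL-7 array 1 (0.0792). Dhrs3 missed it without naive IL-7 array 1 (0.0657) or 2 (0.153), naive IL-4 and IL-7 array 1 (0.0782), memory IL-4 and IL-7 array 2 (0.0869), or memory IL-7 array 1 (0.0572) or 2 (0.15). Tnfrsf18 missed it without naive IL-7 array 1 (0.121) or 2 (0.228), naive IL-4 and IL-7 array 1 (0.0997), memory IL-4 and IL-7 array 1 (0.139) or 2 (0.0869), or memory IL-7 array 1 (0.0572) or 2 (0.267). IL-7 and STAT5 genes were the list that differed, with a mean difference of 0.94, memory less naive (camera adjusted p = 0.00109, and adjusted p = 0.521 with an estimated correlation). Over all genes 1 member, Lta, passed, and 6 were higher and 1 lower when adjusted over the list alone. The list mean was 9.77 in naive and 8.99 in memory cells with IL-7 alone, and 9.64 and 9.81 with both cytokines. The list thus started from unlike levels and ended at similar ones. It did not pass without memory IL-4 and IL-7 array 1 (adjusted p = 0.132). The other lists did not pass with all arrays. Interferon-stimulated genes were higher without naive IL-7 array 1 (0.00665) or memory IL-4 and IL-7 array 2 (0.00335), and the unfolded protein list without naive IL-7 array 1 (0.000677) or naive IL-4 and IL-7 array 2 (0.0248). Cholesterol genes were higher without naive IL-7 array 2 (0.0358), naive IL-4 and IL-7 array 1 (0.0257), memory IL-4 and IL-7 array 2 (0.0236) or memory IL-7 array 1 (0.0394). Without the last array ribosome biogenesis was higher (0.0394) and homing molecules lower (0.0303). None of these lists passed with an estimated correlation (adjusted p 0.179 to 0.979).

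**Figure D4:**
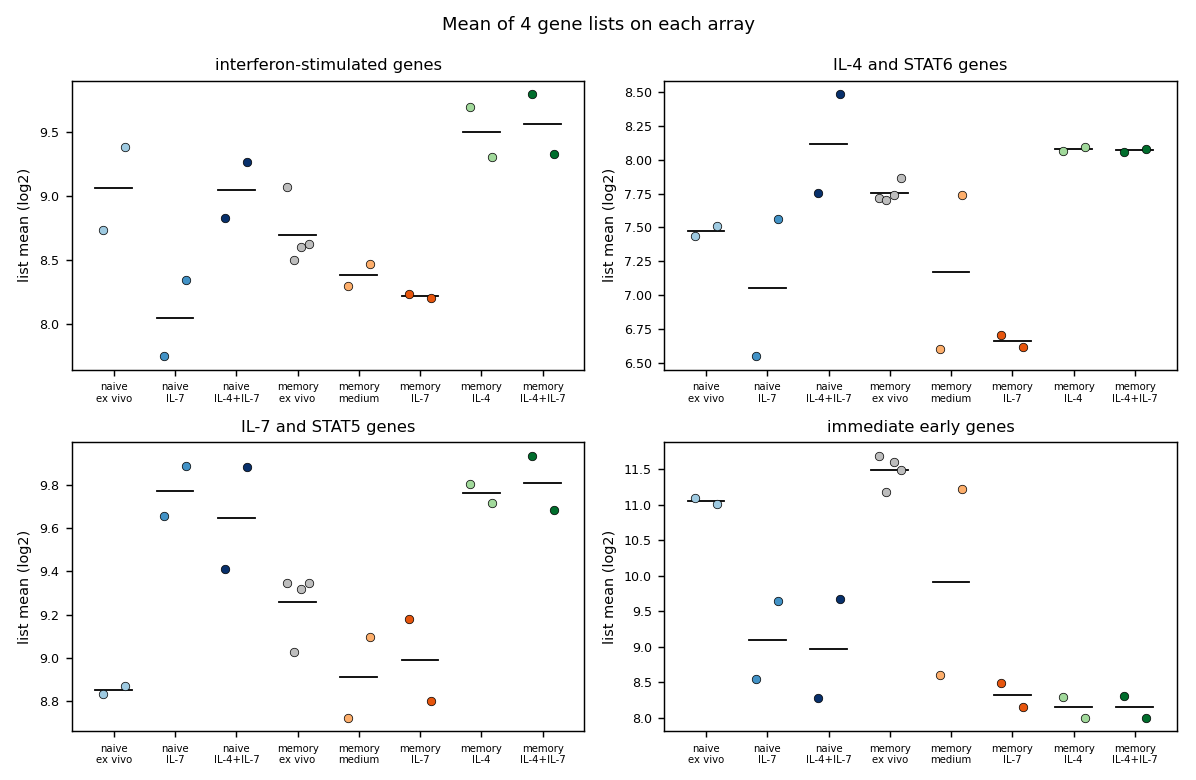
Mean RMA value (log2, vertical axis) of the interferon-stimulated, IL-4 and STAT6, IL-7 and STAT5, and immediate early genes on each of the 18 arrays, by group (horizontal axis); points are arrays and lines are group means. With IL-4 the interferon-stimulated genes changed by means of 1.35 and 1.12 in memory cells and 1.01 in naive cells.

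Against medium, Klrk1 changed by -0.46 (SE 0.23, adjusted p = 0.723, limma, n = 2 and 2), Bcl2 by 0.84 (SE 0.38, adjusted p = 0.723) and Il7r by 0.65 (SE 0.35, adjusted p = 0.723), and none passed, nor did Hcst (-0.71), Il4ra (-1.06), Eomes (-0.20) or Cd8a (0.34). If no gene changed, 688.5 of the 13770 genes would be expected at an unadjusted p under 0.05 in any comparison. With 2 arrays in each group, a count of 0 does not show that nothing changed. The limma count was 0, with 804 genes at an unadjusted p under 0.05, and 0, with 86, without the array labelled memory in medium, replicate 2. Without medium array 1, so that the array labelled replicate 2 alone stood for medium, 2250 genes passed, among them Il4ra (-2.40, adjusted p = 0.00118), Il7r (1.41, adjusted p = 0.00139) and Hcst (-1.18, adjusted p = 0.0435). Without IL-7 array 2, 1 gene passed, Myo6, which is named after its values were seen (2.69, adjusted p = 0.0418). Immediate early genes (mean -1.59, adjusted p = 2e-11), the unfolded protein list (adjusted p = 4.08e-05), ribosome biogenesis (0.000185), cytotoxic effector genes (0.00261) and IL-4 and STAT6 genes (0.0405) were lower with IL-7. None passed with an estimated correlation (adjusted p = 0.557 for each) or without the array labelled memory in medium, replicate 2 (adjusted p = 0.163, 0.41, 0.25, 0.72 and 0.141). Without that array, IL-7 and STAT5 genes were higher (adjusted p = 3.17e-05, and 0.203 with an estimated correlation), and cholesterol genes higher and NK-type receptors lower (both 0.00654, and 0.244 with an estimated correlation). CD4 markers were then higher and red cell markers lower, neither with an estimated correlation. Red cell markers lay far apart on the memory IL-7 arrays (mean 5.55, SD 1.05), so the size of their fall depends on these arrays. Without IL-7 array 1, NK-type receptors (0.00901) and red cell markers (0.00927) were lower. Without IL-7 array 2, IL-7 and STAT5 genes were higher (0.013) and IL-4 and STAT6 genes no longer passed (0.121), and MHC class II markers were lower without medium array 1 (0.0475). With an estimated correlation these lists had adjusted p of 0.351 to 0.695.

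With IL-4 present, the addition of IL-7 gave a limma count of 0 as well, with 286 genes at an unadjusted p under 0.05, and 387 without the array labelled memory in medium, replicate 2. Both numbers lie below the 688.5 expected if no gene changed. Klrk1 changed by -0.11 (SE 0.23), Bcl2 by -0.17 (SE 0.38) and Il7r by -0.21 (SE 0.35), and none passed (smallest adjusted p over all genes 0.9998). No list passed with all arrays, and interferon-stimulated genes were higher without IL-4 and IL-7 array 2 (mean change 0.30 above that of all genes, adjusted p = 0.00716, and adjusted p = 0.991 with an estimated correlation). The interaction of IL-4 and IL-7 in memory cells also had a count of 0 in limma, with 650 genes at an unadjusted p under 0.05, or 234 without that array; Klrk1 had an interaction of 0.35 (SE 0.33, adjusted p = 0.859). Without medium array 1 the count was 1298, with Il4ra (2.44, adjusted p = 0.00976) and Il7r (-1.62, adjusted p = 0.00615) past the threshold. Immediate early genes (mean 1.59, adjusted p = 1.2e-06) and the unfolded protein list (mean 0.54, adjusted p = 0.00455) had a positive interaction, but neither with an estimated correlation (adjusted p = 0.874 for both) nor without the array labelled memory in medium, replicate 2 (adjusted p = 0.439 and 0.647), and the latter not without IL-4 array 2 (0.139). Ribosome biogenesis had a positive interaction without IL-4 and IL-7 array 2 (0.0394), IL-4 array 1 (0.0135), IL-7 array 1 (0.0175) or medium array 1 (6.94e-05). So had cytotoxic effector genes without IL-4 and IL-7 array 2 (0.0457), IL-4 array 1 (0.0471) or medium array 1 (0.00147). Interferon-stimulated genes had 1 without IL-4 and IL-7 array 2 (0.00398) or IL-4 array 1 (0.0135), as did IL-4 and STAT6 genes without medium array 1 (0.00224). None of these held with an estimated correlation (adjusted p 0.458 to 0.921).

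Ex vivo, Ifng was higher in memory than in naive cells by 7.98 (SE 0.51, adjusted p = 8.87e-07, limma, n = 4 and 2), at a mean of 12.03 against 4.05. The chemokine gene Ccl5 was higher by 6.12 (SE 0.30, adjusted p = 8.71e-08), the chemokine receptor gene Cxcr3 by 5.44 (SE 0.29, adjusted p = 1.35e-07), the transcription factor gene Tbx21 by 4.83 (SE 0.67, adjusted p = 0.000879) and the death ligand gene Fasl by 4.74 (SE 0.49, adjusted p = 7.58e-05). Klrk1 was 7.76-fold higher, by 2.96 (SE 0.20, adjusted p = 1.21e-06), and the NKG2A gene Klrc1 was higher by 2.55 (SE 0.35, adjusted p = 0.000831). The naive means of Ifng (4.05), Tbx21 (3.65) and Klrc1 (2.77) lay under the filter value of 4.06, and that of Klrk1 next to it. The size of these 4 differences is thus uncertain. Hcst (0.07, adjusted p = 0.923), Il4ra (0.41, adjusted p = 0.702), Eomes (1.22, adjusted p = 0.294), Il7r (0.19, adjusted p = 0.771), Bcl2 (0.86, adjusted p = 0.199) and Cd8a (-0.16, adjusted p = 0.703) did not pass.

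H2-Q10, whose probe set may share sequence with other class I genes, S100a6, the cadherin gene Cdh1 and the asparagine synthetase gene Asns were higher in memory cells by 4.72, 4.32, 3.54 and 3.29, and Cxcr5 was 8.03-fold higher. The largest falls were in Sox4 at -4.99 (SE 0.40, adjusted p = 6.93e-06), the RANK ligand gene Tnfsf11 at -4.13 (SE 0.87, adjusted p = 0.024), Hacd1 at -3.55 (SE 0.70, adjusted p = 0.0161) and Tcf4 at -3.41 (SE 0.53, adjusted p = 0.00222). The naive mean of Cdh1 (3.61) and the memory means of Tnfsf11 (3.10) and Hacd1 (3.23) lay under the filter value. Ptprf, Trat1, Cd81, Ikzf2, Mtss1 and Basp1 were lower by log2 changes of -3.27 to -3.04. Tnfsf11 missed the threshold without naive array 1, naive array 2, memory array 1 or memory array 2 (adjusted p = 0.19, 0.152, 0.0646 and 0.0527), and Hacd1 without naive array 1 or 2 (0.195 and 0.0791). Asns missed it without naive array 1 (0.0568) and Tcf4 without naive array 2 (0.0518); the other named genes passed without each of the 6 arrays in turn. In all 266 genes passed, 141 higher and 125 lower in memory cells, and 605 (262 higher and 343 lower, all 266 among them) without the array labelled memory in medium, replicate 2. The count was 112 without naive array 1 and 114 without naive array 2.

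Of 24 memory CD8 genes 7 were higher and 0 lower, 11 when adjusted over the list alone (mean 1.43, adjusted p = 4.75e-10, and adjusted p = 0.0626 with an estimated correlation), with Cxcr3, Tbx21 and S100a6 in front. Cytotoxic effector genes (3 of 19 higher and 0 lower, 8 when adjusted over the list alone; mean 1.61, adjusted p = 5.17e-07, and adjusted p = 0.0905 with an estimated correlation) and NK-type receptors (2 of 15 higher and 0 lower, 6 when adjusted over the list alone; mean 0.83, adjusted p = 1.82e-05, and adjusted p = 0.0626 with an estimated correlation) were higher. Inhibitory receptors were higher (2 of 10, 3 when adjusted over the list alone; mean 0.68, adjusted p = 0.00578, and adjusted p = 0.0626 with an estimated correlation), through Nt5e by 2.65 and Ctla4 by 2.39. IL-7 and STAT5 genes were higher (adjusted p = 0.0337, and adjusted p = 0.247 with an estimated correlation) but not without naive array 1, naive array 2, memory array 1, 3 or 4 (adjusted p 0.0515 to 0.0934). Naive CD8 genes were lower by the mean (-0.53) and the test (adjusted p = 0.00626, and adjusted p = 0.0905 with an estimated correlation) but not by the median (0.01). Sox4 and Ccr9 (-2.97) fell, and 4 fell when adjusted over the list alone. Interferon-stimulated genes were lower in memory cells (0 of 26 higher and 2 lower, 3 when adjusted over the list alone; mean -0.36, adjusted p = 0.00626, and adjusted p = 0.465 with an estimated correlation), with Ifit1 and Oasl1 (-1.07) past the test over all genes, but the list did not pass without naive array 2 (adjusted p = 0.596).

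Markers of other cells were higher in the ex vivo memory arrays: B cells (mean 0.70, adjusted p = 0.00237), cells with MHC class II (0.73, adjusted p = 0.00298), NK cells (0.80, adjusted p = 0.00626; all 4 members tested are also in the list of NK-type receptors), red cell precursors (2.04, adjusted p = 0.0219), myeloid cells (0.35, adjusted p = 0.0327) and CD4 T cells (0.35, adjusted p = 0.0406). With an estimated correlation these had adjusted p of 0.0905, 0.195, 0.091, 0.0905, 0.0961 and 0.105. Ms4a1 (1.55, adjusted p = 0.0415) was the member that passed over all genes, from a naive mean of 3.30, under the filter value. Myeloid markers did not pass without naive array 1 (adjusted p = 0.109) or memory array 4 (0.0575). Red cell markers did not pass without naive array 2 (0.0789) or memory array 1 (0.0511). CD4 markers did not pass without naive array 1 (0.0546), naive array 2 (0.0934), memory array 1 (0.0515), memory array 2 (0.0546) or the array labelled memory in medium, replicate 2 (0.0592). CD8 markers (adjusted p = 0.452) did not pass, and platelet markers (adjusted p = 0.0684) did without memory array 3 (0.0439). Proliferation genes (adjusted p = 0.331) were lower without naive array 1 (0.00544). Neither passed with an estimated correlation (adjusted p = 0.108 and 0.266).

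In naive cells with IL-7 against ex vivo, Bcl2 rose 5.35-fold, by 2.42 (SE 0.38, adjusted p = 0.0024, limma, n = 2 and 2), and Lta by 3.84 (SE 0.36, adjusted p = 0.000101). No naive cells were measured after culture in medium alone. Changes from culture itself and from IL-7 thus cannot be told apart for the genes, counts and lists of this comparison. Etfbkmt, AA467197, D630039A03Rik and Ecm1 rose by 4.64, 4.47, 4.25 and 3.62. The AP-1 genes Fosl2 and Fosb fell by 6.07 (SE 1.31, adjusted p = 0.0109) and 5.51 (SE 0.95, adjusted p = 0.00391), the transcription factor gene Klf4 by 5.96 (SE 0.83, adjusted p = 0.00144), Ramp3 by 5.96 and Frmd4b by 5.49. Frmd4b had means of 9.76 ex vivo, 4.27 with IL-7 and 10.36 with IL-4 and IL-7. Klrk1 (-0.08, adjusted p = 0.886) did not pass, nor did Il4ra (-0.45), Eomes (0.24) or Il7r (-0.44). Hcst (-1.05, adjusted p = 0.0633) and Cd8a (0.62, adjusted p = 0.0995) passed without the array labelled memory in medium, replicate 2 (adjusted p = 0.0245 and 0.0384). Fosl2 missed the threshold without each of the 4 arrays (adjusted p 0.0538 to 0.0674). Etfbkmt missed it without ex vivo array 2 (0.0532), and Ramp3 and Frmd4b without ex vivo array 2 (0.0635 and 0.067) or IL-7 array 1 (0.0547 and 0.0835).

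In this comparison 1762 genes passed, 964 up and 798 down, and 2772 (1678 up and 1094 down) without the array labelled memory in medium, replicate 2. The count was 796 (387 up and 409 down) without ex vivo array 1, 353 (155 and 198) without ex vivo array 2, 694 (392 and 302) without IL-7 array 1 and 258 (96 and 162) without IL-7 array 2. IL-7 and STAT5 genes rose (7 of 21 up and 0 down, 9 and 1 when adjusted over the list alone; mean 0.92, adjusted p = 0.00321, and adjusted p = 0.33 with an estimated correlation), among them Socs2 by 2.96, Il2ra by 2.90 (from an ex vivo mean of 3.55, under the filter value) and Myc by 2.64. Interferon-stimulated genes fell (0 of 26 up and 10 down, 11 when adjusted over the list alone; mean -1.02, adjusted p = 1.7e-08, and adjusted p = 0.33 with an estimated correlation), with Rsad2 at -3.36, Oasl2 at -2.14, Mx1 at -1.75 and Irf7 at -1.67. Immediate early genes fell (0 of 22 up and 6 down, 12 when adjusted over the list alone; mean -1.96, adjusted p = 8.72e-08, and adjusted p = 0.476 with an estimated correlation). Naive CD8 genes (0 up and 4 down; adjusted p = 0.00306, and adjusted p = 0.274 with an estimated correlation) and homing molecules (0 up and 4 down; adjusted p = 0.0141, and adjusted p = 0.33 with an estimated correlation) were lower, with Itgae at -2.15, Sox4 at -1.89 and Cxcr4 at -2.55. Other lists passed without single arrays: IL-4 and STAT6 genes without IL-7 array 2 (adjusted p = 0.00246) or without the array labelled memory in medium, replicate 2 (0.0381), and cholesterol genes without ex vivo array 2 (0.0462). So did cholesterol, cytotoxic effector, memory CD8 and proliferation genes without IL-7 array 2 (0.0344, 0.0384, 0.0344 and 0.0344), and proliferation genes without ex vivo array 1 (0.00541). None of them passed with an estimated correlation (adjusted p 0.265 to 0.634).

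The Gapdh 3' minus 5' difference, a measure of RNA quality, was 2.07 to 2.62 on ex vivo memory arrays, 3.16 on medium array 1 and 2.35 on the array labelled memory in medium, replicate 2. In memory cells, medium alone against ex vivo gave a limma count of 0 with all arrays, with 1364 genes at an unadjusted p under 0.05. Without the array labelled memory in medium, replicate 2, 2257 genes passed, 1484 up and 773 down, from 1 medium array against 4 ex vivo arrays. By the same rule, applied after the values were seen, the largest falls were then in the nuclear receptor genes Nr4a2 (-8.09, SE 1.39, adjusted p = 0.00131), Nr4a1 (-7.13) and Nr4a3 (-6.49), in Fosl2 (-6.64, SE 0.57, adjusted p = 8.39e-06) and in Frmd4b (-5.96). The largest rises were in 2010315B03Rik (3.83, SE 0.45, adjusted p = 8.67e-05), the potassium channel gene Kcna2 (3.54), D930003E18Rik (3.53), Etfbkmt (3.48) and Carf (3.47). Nr4a2 on medium array 1 (3.67) and the ex vivo means of 2010315B03Rik (3.45) and D930003E18Rik (3.75) lay under the filter value. Frmd4b on medium array 1 (4.065) lay next to it. The size and rank of these changes are thus uncertain. Nr4a1 stood at 5.51 on medium array 1, at 12.60 on the array labelled replicate 2 and at 12.64 (SD 0.15, n = 4) ex vivo. Klrk1 (-0.09, SE 0.20, adjusted p = 0.916), Hcst, Eomes, Bcl2 and Cd8a did not pass with or without that array. Il4ra (-0.81, adjusted p = 0.613) and Il7r (0.37, adjusted p = 0.693) passed without it (-2.14, adjusted p = 0.00126, and 1.13, adjusted p = 0.00304). With all arrays 12 lists were lower in medium, led by immediate early genes (mean -1.58, adjusted p = 7.7e-13), the unfolded protein list (-0.54, adjusted p = 9.53e-06), cytotoxic effector genes and ribosome biogenesis (both 0.000178). None passed with an estimated correlation (smallest adjusted p = 0.328). Without the array labelled memory in medium, replicate 2, these 4 lists passed (adjusted p = 3.45e-15, 9.37e-07, 1.35e-05 and 2.29e-07), with adjusted p of 0.203 to 0.419 with an estimated correlation. Without medium array 1 they did not pass (0.446, 0.752, 0.752 and 0.446), nor did IL-4 and STAT6 genes (0.613), NK-type receptors (0.0546), cholesterol genes (0.898), IL-7 and STAT5 genes (0.72), glycolysis (0.0546), interferon-stimulated genes (0.596) or proliferation (0.0546). NK-type receptors and NK cell markers did not pass without the array labelled memory in medium, replicate 2 (0.339 and 0.344), and MHC class II markers did (0.0198). Without ex vivo array 1, NK-type receptors (0.145), IL-7 and STAT5 genes (0.0999) and interferon-stimulated genes (0.0999) did not pass. Without ex vivo array 3 or 4, cholesterol genes (0.119 and 0.0988) and IL-7 and STAT5 genes (0.0801 and 0.0547) did not, while MHC class II markers did (0.0245 and 0.0205). With an estimated correlation the MHC class II markers did not pass without any of these arrays (adjusted p = 0.466, 0.404 and 0.343).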

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

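All tests of explanations in this part were chosen after the results they concern were seen. The array labelled memory in medium, replicate 2, stands with the ex vivo memory arrays. On a scale set by 216 genes, with 0 for ex vivo memory cells and 1 for memory cells cultured with a cytokine, it had a position of -0.0115, within the ex vivo range of -0.0505 to 0.0526. These values are consistent with an ex vivo memory array under a medium label. A swap between the groups is argued against, since the highest ex vivo memory array stood at 0.0526. Medium that keeps the ex vivo profile is argued against by the other medium array, at 0.874, only if that array is rightly labelled. Over the genes tested, medium array 1 correlated with the memory IL-7 arrays at r = 0.9959 and 0.9958, above these arrays with each other (0.9946). On the scale it stood below them (0.954 and 0.964). Its label was not tested. A swap with a sample outside the series, a second array of the RNA of ex vivo memory array 2, or a culture that went otherwise, was not tested.

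Sex-linked genes varied among the memory arrays. Xist was between 4.35 and 5.27 on the naive arrays and 4.40 on ex vivo memory array 3, and 11.78 to 12.88 on the other memory arrays; its ex vivo difference was 5.86 (SE 1.58, adjusted p = 0.0815). The sex of the animals as the whole cause of the memory against naive difference is argued against by array 3: over the 244 genes past the threshold without it, it kept a median of 0.870 of the difference (quartiles 0.695 and 1.03), and all 244 lay on the same side of naive cells. The sex of the animals is not given in the sources used here, and a part played by it in single genes stays open and untested.

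The interferon-stimulated list was higher with IL-4 in memory cells with and without IL-7 and in naive cells, with 10, 8 and 5 of 26 members past the threshold, but not with an estimated correlation (adjusted p = 0.104, 0.147 and 0.17). Ifng message of the cultured cells cannot be told apart from a direct IL-4 response: Ifng changed by 0.377 (SE 0.59), -0.72 and -0.10, none past the threshold in limma (adjusted p = 0.799, 0.666 and 0.984). With IL-7 alone Ifng was 5.66 higher in memory than in naive cells, while the list mean differed by 0.17 (SE over members 0.115). That contrast is between cell types and not between cultures with and without IL-4, so it does not decide the question. Nor can cells with MHC class II, whose list changed by a mean of 0.258, -0.22 and -0.15 in these comparisons, none past the test (camera adjusted p = 0.532, 0.672 and 0.559). The sign of the -0.22 turned without the array labelled memory in medium, replicate 2. H2-DMa rose by 3.19, 2.85 and 2.59. Type I interferon message cannot be told apart either: 2 type I interferon genes, Ifna1 and Ifna9, lay above the filter on at least 2 arrays, the highest value of Ifna1 being 5.32. Neither rose past the threshold in an IL-4 comparison. Their values lay low (Ifna9 at most 4.20, filter value 4.06), where a change could hardly show, so this does not decide the question. In naive cells the list mean with both cytokines (9.05) stood near that ex vivo (9.06). In memory cells it was 9.57 with both cytokines and 8.70 ex vivo. A direct IL-4 response stays open as a hypothesis and was not tested.

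A sample far from the others was found for 6 of 55 values tested in the group of 4 ex vivo memory arrays, where chance flags about 1 in 20. Cdh1 was 7.47 on array 4 (others 7.01 to 7.08), Hcst 9.44 on array 4 (others 10.29 to 10.44), Hacd1 4.255 on array 1 (others 2.82 to 2.95) and Klrk1 6.53 on array 3 (others 7.18 to 7.24). The mean of the IL-7 and STAT5 genes was 9.03 on array 2 (others 9.32 to 9.35), and that of the red cell precursor markers 8.70 on array 1 (others 6.51 to 6.80).

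A difference between groups, tested as a contrast of the IL-4 responses of memory and naive cells, was found for Ecm1 (3.76), Myo6 (3.59), Gm17767 (3.32), D630039A03Rik (3.31), Lta (3.08), Tnfrsf18 (2.20), Ptpn3 (-2.81), H2-Q2 (-2.28), Papss2 (-2.05) and Dhrs3 (-1.76), and for the IL-7 and STAT5 list (0.94), the list neither with an estimated correlation (adjusted p = 0.521) nor without memory IL-4 and IL-7 array 1 (0.132). The sizes for Ptpn3, Dhrs3, H2-Q2 and Gm17767 are uncertain, since group means lay under the filter value. Ecm1, D630039A03Rik and the IL-7 and STAT5 list started from unlike levels in memory and naive cells with IL-7 alone. The interaction of IL-4 and IL-7 in memory cells was found for the unfolded protein list (0.54) and immediate early genes (1.59), and neither was kept with an estimated correlation (adjusted p = 0.874 for both) or without the array labelled memory in medium, replicate 2.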

How the results depend on the processing

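Leaving out the array labelled memory in medium, replicate 2, in every comparison, alone and with a replicate block, was chosen after the data were seen; the other alternatives were planned. The named genes followed here are the largest rises and falls and the genes named in every comparison, without members named only for a list. None of them past the threshold reversed its direction. Of 105 named gene results past the threshold, 105 stayed there with cyclic loess and with a minimum log2 change of 1, 103 with no filter, 102 with trend and robust variances, 99 with the mean of probe sets, 92 with a block, 76 with only the groups compared and 103 without that array; 102 of 103 stayed with a stricter filter, and 367 of 476 without 1 other array. Arrays are few, and the size of changes from means under the filter value is uncertain. Arrays with the same replicate number share no stated origin, though Eif2s3y and Kdm5d in memory cells, and list means in naive cells, followed the number. Correlations between groups of the residuals by number ran from -0.125 to 0.511, and from 0.251 to 0.447 among memory groups with a cytokine. Those between these groups and medium, 0.00818 to 0.0974, say little. The medium residuals are set by the gap between array 1 and the array labelled replicate 2, which has an ex vivo profile. Each naive IL-4 and IL-7 array correlated best with the naive IL-7 array of its number (r = 0.978 and 0.989), above the other array of its group (0.975). The split of Eif2s3y by number in memory cells goes with populations shared by number there. In naive cells the residuals went together between the cultured groups (0.511) but not between ex vivo and IL-4 and IL-7 (-0.125). The main fit leaves any such pairing out, so its SEs, p-values and counts do not allow for it. With a block, the named results that missed the threshold were Mir1931 for IL-4 in memory cells with IL-7, Fosb, Rgs2 and Fos without IL-7, and Frmd4b, Spsb1, Ctla2a, Vim and Fxyd7 in naive cells. So did Asns and Hacd1 between memory and naive cells, and Papss2 and Dhrs3 in the difference. In naive cells with IL-4, memory CD8 genes and ribosome biogenesis stayed lower with a block (adjusted p = 0.0327 and 0.00261) and the unfolded protein list did not pass (0.458). Between arrays with the same number their means changed by -0.47 and -0.18, -0.36 and -0.26, and 0.14 and 0.12.

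The number of genes past the threshold, without each array in turn, ran from 76 to 538 for IL-4 in memory cells with IL-7 (249 with all), from 73 to 2364 without IL-7 (267), from 50 to 672 in naive cells (173), from 0 to 2250 for IL-7 without IL-4 (0), from 112 to 605 for memory against naive cells (266), from 0 to 2257 for culture of memory cells in medium (0), from 258 to 2772 for culture of naive cells (1762), from 2 to 368 for the difference of the IL-4 responses (10) and from 0 to 1298 for the interaction (0). It stayed 0 for IL-7 with IL-4. With only the groups compared it was 1035, 9 and 29 for IL-4 in memory cells with IL-7, without IL-7 and in naive cells, and 2 for the difference (Ecm1 and D630039A03Rik), where fewer arrays set the spread. The difference had 6 genes with the stricter filter, memory against naive cells 163 with a block (105 of the 266 among them), the difference 12 with a block (7 of the 10 among them), and culture of naive cells 1092 with a minimum log2 change of 1, which by construction drops smaller changes. With a block and without the array labelled memory in medium, replicate 2, the counts were 792, 339, 542, 1957, 3178 and 67 for IL-4 in memory cells with IL-7, IL-4 in naive cells, memory against naive cells, culture of memory cells, culture of naive cells and the difference. The causes of the other changes were not tested.

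Lists changed direction by the test with a medium array left out (mean change less that of all genes). For IL-4 in memory cells without IL-7, cytotoxic effector genes were at 0.375 without the array labelled memory in medium, replicate 2, and -0.801 without medium array 1, the unfolded protein list at 0.404 and -0.547, and ribosome biogenesis at 0.126 (adjusted p = 0.214) and -0.765. For IL-7 without IL-4, cytotoxic effector genes were at -0.0156 (test direction higher, adjusted p = 0.72) and -1.19, ribosome biogenesis at 0.0635 (0.25) and -0.828, and IL-4 and STAT6 genes at 0.103 (0.141) and -1.16. For culture of memory cells in medium, ribosome biogenesis was at -0.799 and 0.0923 (0.446), and IL-4 and STAT6 genes at -1.21 and 0.0594 (0.613). With a block and without the array labelled replicate 2, cytotoxic effector genes, the unfolded protein list and ribosome biogenesis were at 0.426, 0.408 and 0.158 for IL-4 without IL-7. For IL-7 without IL-4, cytotoxic effector, interferon-stimulated, ribosome biogenesis and IL-4 and STAT6 genes were then at 0.0347, 0.144, 0.0956 and 0.111. The causes were not tested.

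Of 58 list calls, 0 stayed with an estimated correlation; without each array in turn there were 48 to 64. Of 52 list calls gained without 1 array, 0 held with an estimated correlation (smallest adjusted p = 0.0609). With a block 51 of the 58 list calls stayed, 7 were lost and 5 gained. With the mean of probe sets 52 stayed, with no filter or cyclic loess 54, and with only the groups compared 55. With trend and robust variances all 58 stayed, and with a stricter filter 49 of 55. The correlation of the IL-4 responses of memory cells with and without IL-7 was 0.893, from 0.771 to 0.955 without each array and 0.514 over all genes. Between memory and naive cells it was 0.701, from 0.645 to 0.732 and 0.313.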

Other observations

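The genes of this paragraph were chosen after their values were seen. Among the 54 genes that rose in all 3 IL-4 comparisons were Stat2, Irgm1, Ifi47, Parp9 and Sting1, genes of interferon and innate signalling, and Ikzf3, Rasgrp1, Map3k8, Cst7, H2-DMa, Trat1 and Cdh1. Among the 10 that fell were App, Cd55, Cd84, Atp8b4, Rab11fip4 and Rcn3. Trat1 thus rose with IL-4, and was lower in memory than in naive cells ex vivo by a log2 change of -3.22.

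Eif2s3y, a gene of the Y chromosome, was 9.24 to 10.20 on the memory arrays numbered 1 and 6.02 to 6.78 on those numbered 2, cultured or ex vivo, including the array labelled memory in medium, replicate 2 (6.02). It was 10.13 on ex vivo memory array 3, 2.88 on ex vivo memory array 4 and 10.18 to 11.28 on the naive arrays.

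For IL-4 and IL-7 in memory cells, each against the same medium arrays, the changes over all genes had r = 0.597, where 100 simulations of unchanged groups with shared medium arrays had a highest value of 0.527. These simulations gave all groups the same spread per gene. The medium arrays differed far more (SD of the difference 0.742) than the IL-7 arrays (0.262) and the IL-4 arrays (0.316). The simulated value may thus be too low, and no shared response can be read from r above it. Without the array labelled memory in medium, replicate 2, r was 0.374 and the simulated mean 0.666.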
